A study of Caenorhabditis elegans with 2 samples.

How the data were processed

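The data are peak lists from ChIP-seq of GFP-tagged F57C9.4 in whole young adult worms, with 1 library for each of 2 biological replicates, numbered 5 and 6 in the labels. Per the labels, chromatin was fragmented by sonication and precipitated with an antibody against GFP, and a control experiment is named as possible. Per the file headers and accompanying text, each list is in narrowPeak format on build ce10 or ce11. The lists before IDR were made from the alignments of a replicate, or of both replicates pooled, together with 1 further file per build whose kind is not stated. The IDR list was derived from the lists of the replicates and the pooled list. The aligner, the peak caller and their versions are not given in the sources used here.

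The deposited signal value of each interval comes from the authors' peak caller and was used only to rank and describe intervals within a list, since its scale differed between lists: the median was 25.8 in the pooled list, 18.5 in replicate 5 and 12.3 in replicate 6. The deposited −log10 q-value was used only to describe the lists, and the q-value of the IDR peaks ran from 0.00493 to 0.0237. The deposited lists give another value, the summit offset from the interval start, from which the summit position was computed. The score and p-value columns held a single constant value and were not used. Each list before IDR held exactly 30000 intervals, as a limit on list length gives, with pooled q-values up to 0.906, so most of these intervals are background by design and serve here as what could have been called. Intervals were 101 to 404 bp wide in the IDR list (median 404), which limits the resolution of a summit.

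All 360 IDR peaks on ce11 were intervals of the pooled list, and all 360 were its best-ranked ones. The list is therefore ranked by pooled signal, and a peak in it need not rank high in each replicate. The ce10 list held 354 peaks, of which 349 matched a ce11 peak on chromosome and on signal within 0.1%. Coordinates were not converted between builds, and annotation was applied to ce11 lists only. Annotation was Ensembl release 115 for WBcel235, the same assembly as ce11, with 46890 genes, of which 19973 are protein-coding. Read counts were not analysed here, so depth per library is unknown and no counting error can be given for a signal value. Wilson 95% intervals on shares of peaks cover counting error over peaks only.

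The following choices were made before the data were examined, except where stated. A summit counted as found in a replicate when it lay in an interval among the 360 best of that replicate. The chance share came from 1000 random placements on the same chromosome. Distances were to annotated transcript starts, with a window of 500 bp. A gene was a target when an IDR summit lay within the window of a start. Gene lists (24 defined by gene symbol patterns among protein-coding genes and 6 by annotated class) were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment, against genes of the same class with a pooled summit in the window, and for non-coding classes against all genes with one. Odds ratios have 0.5 added to each cell. Chromosomes were tested against the 29605 pooled summits outside IDR peaks. GC content within 100 bp of summits was compared by a two-sided permutation test with 100000 resamples. Presence of each of 2080 6-mers within 50 bp of summits was compared with that at points 300 bp to either side. Named peaks were the 25 with the highest signal value that also had an interval among the 360 best of both replicates, each assigned to the protein-coding gene with the nearest start within 1000 bp, otherwise to the gene holding the summit, otherwise by position. Up to 4 target genes of each list with the highest signal were also named, with F57C9.4 and unc-119. The neighbouring non-coding RNA genes of these peaks were named after their values were seen. So were htp-3, lin-54, rpl-7A, rpl-12, rps-1, rps-19, rps-26, hsr-9, tmem-107 and the remaining low-count members given in full.

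Alternatives covered the stronger 180 peaks, the 360 best intervals of a single replicate in place of the IDR peaks (without replicate 5 or 6), other windows, overlaps, list depths, backgrounds and the ce10 lists. Alternatives added after seeing the data were peaks among the 360 best of both replicates, peaks with no small RNA start, a background without piRNA genes, the agreement over all pooled intervals, and chromosomes without summits near tRNA starts. The gene list and 6-mer tests were tested on simulated data. In 20 simulations a list of 200 genes with 10% made targets was called each time and no random list was called, at a raw Fisher p under 0.05. No adjustment over lists was applied there, and most lists tested here held far fewer genes. The simulations therefore do not give the sensitivity of the reported gene list calls. A 6-mer planted in 10% of windows was called in 20 of 20, and with none planted a median of 2 and at most 13 of 2080 6-mers were called. The simulated summits were drawn at random from pooled summits outside IDR peaks, without matching the GC content of IDR summits or their flanks. These counts therefore do not give the number of false calls among the 6-mers reported at IDR peaks. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.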

Results

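F57C9.4 binding was profiled by chromatin immunoprecipitation with sequencing (ChIP-seq) in whole young adult Caenorhabditis elegans. In this assay, crosslinked and sheared chromatin is precipitated with an antibody and the DNA that comes down is sequenced, so that bound regions appear as local peaks of reads. The worms were of strain OP550, which carries the integrated transgene wgIs550 encoding F57C9.4 with a GFP and FLAG tag at its C terminus, in an unc-119 mutant background. They were of mixed sex and were collected 66 h after release from a starved L1 synchronisation. Chromatin was precipitated with an antibody against GFP. The labels describe 1 group with 2 biological replicates, numbered 5 and 6, and no second condition, so the questions the design poses are where the tagged protein was found and how alike the replicates were. The authors' list after the irreproducible discovery rate (IDR) procedure, which compares the ranks of peaks between replicates, held 360 peaks on build ce11. The lists made before IDR held 30000 intervals each for replicate 5, for replicate 6 and for the pooled replicates. The read depth of the libraries is unknown, because the lists hold no read counts.

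The strongest peak lay in the 5′ untranslated region of zip-11, a bZIP transcription factor gene, with its summit at IV:3311435, 159 bp from a start of the gene (IV:3311276-3313189). Its pooled signal value was 579 and it ranked 1 in each replicate. The next peak, at V:5780909, lay 13 bp from a start of F44E7.5 with a signal of 459, with starts of the non-coding RNA gene F44E7.13 at 40 bp and of the microRNA gene cel-mir-253 at 293 bp. The remaining peaks were much weaker, from 250 at rpl-3 (III:3867582, 272 bp upstream of the start of this gene for a protein of the large ribosomal subunit) down to 66.8. The median over the 360 peaks was 81.5. All positions are on ce11, counted from 1, and the signal values are those of the authors' peak caller.

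Several of the 25 strongest peaks that ranked among the 360 best intervals of both replicates lay at genes of small non-coding RNAs. The peak at I:4172351 (signal 217) was 145 bp from sls-2.4, a gene of the SL2 spliced leader RNA, which is trans-spliced onto messages of downstream operon genes, 45 bp from the non-coding RNA gene R12E2.18 and 762 bp from egg-5. Peaks at II:5844923 (signal 146) and II:5543814 (signal 137) lay 58 bp from sls-2.1 and 216 bp from sls-2.2, with the non-coding RNA gene C17C3.23 nearer to the latter summit at 116 bp. In an intron of pxn-1, the summit at V:8500561 (signal 195) was 18 bp from the snoRNA gene ZK994.7. Within frm-7, the summit at V:12303638 (signal 194) fell in the snoRNA gene C51F7.4, 39 bp from its start. An intronic summit in cutl-18 at V:11314204 (signal 147) was 54 bp from the snoRNA gene T03F7.8. The peak at I:13463999 (signal 190) was in a non-coding exon inside the span of ints-8, 44 bp from rpr-1, the gene of the RNase P RNA. On chromosome X the summit at X:9743691 (signal 136), in an intron of him-4, was 56 bp from the tRNA gene WBGene00014334 and 13 bp from the non-coding RNA gene F15G9.8.

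Other peaks of this set were assigned to protein-coding genes, except that at IV:2219596. Summits were 50 bp from the start of tasp-1 (III:10759257, signal 184), 12 bp from kin-14 (I:7079563, signal 159), 17 bp from cux-7 (III:7520862, signal 157) and 27 bp from prmt-5, a protein arginine methyltransferase gene (III:5230597, signal 145). The summit at IV:4750064 (signal 160) lay between Y17G9B.5, 176 bp away, and rpl-20, 286 bp away. A summit at II:11759486 (signal 151) was 175 bp from F44E5.4, a gene of the hsp-70 family, and F56G4.6 had a summit 103 bp from its start (I:11374437, signal 145). The peaks assigned to mdt-26, a Mediator subunit gene, and cbp-1, the gene of the CBP/p300 acetyltransferase, were farther from a start, at 592 bp (II:5661786, signal 191) and 919 bp (III:9765590, signal 136). The summit at IV:654930 (signal 142) was 354 bp from rpl-15. In dos-3 the summit fell in a coding exon (III:835988, signal 168) and in zig-11 in the 3′ untranslated region (V:1875715, signal 133). Inside the span of ppfr-1 the summit at I:9383149 (signal 142) fell in an exon of a non-coding gene. It was 21 bp from a start of the non-coding RNA gene F16A11.7. Near ZK1248.17 the nearest start of that gene was 618 bp from the sls-2.1 summit. The summit at IV:2219596 (signal 136) had no protein-coding start within 1000 bp and lay outside annotated genes.

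The replicates shared a few of their strongest sites but differed in the order of many others. zip-11, F44E7.5 and sls-2.4 ranked 1, 2 and 4 in replicate 5 and also 1, 2 and 4 in replicate 6, and rpl-3 ranked 3 and 5. Other strong peaks differed more: that at tasp-1 ranked 23 in replicate 5 and 3 in replicate 6, and that at F44E5.4 ranked 8 and 109. Of the 360 IDR peaks, 257 had their summit in an interval among the 360 best of replicate 5 (71.4%, 95% Wilson interval 66.5 to 75.8) and 215 in one of replicate 6 (59.7%, 54.6 to 64.7). Random placement of the summits on the same chromosomes gave a mean of 0.524 and 0.542 such peaks, and at most 4 and 5 in 1000 placements. The IDR peaks are the best of a list pooled from these same replicates, so overlap above random placement is partly built in. It does not measure reproducibility. Compared directly, 139 of the 360 best summits of replicate 6 (38.6%) lay in an interval among the 360 best of replicate 5. In the other direction there were 143 (39.7%). Both replicates held 144 of the IDR peaks among their 360 best (40%), replicate 5 alone 113, replicate 6 alone 71 and neither 32. Among weaker peaks, that at atf-7 (III:4498486) ranked 100 in replicate 5 and 8221 in replicate 6, while that at egl-30 (I:1835587) ranked 2300 and 66.

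**Figure D1:**
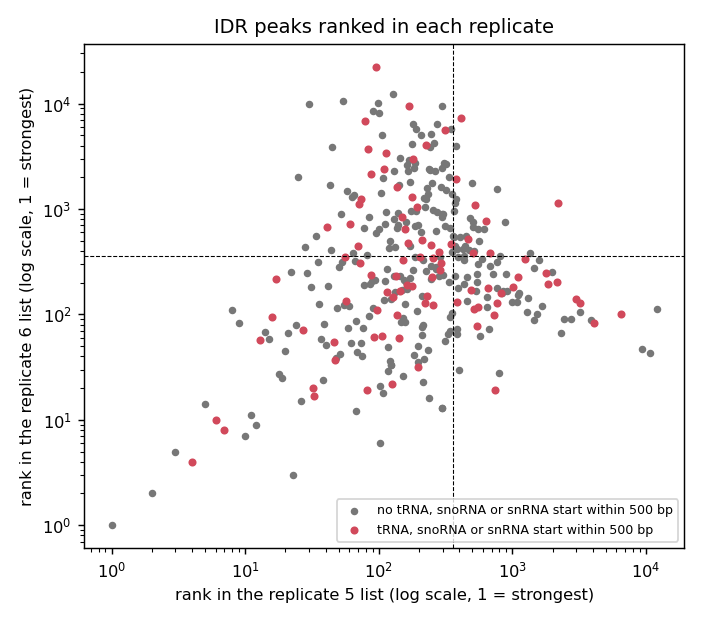
Rank of each IDR peak in the list of replicate 5 (horizontal, log scale) and of replicate 6 (vertical, log scale), with rank 1 the strongest; each point is 1 of the 356 peaks found in both lists, and dashed lines mark rank 360. Red points have a tRNA, snoRNA or snRNA start within 500 bp. A few of the strongest peaks lie near the diagonal, and 144 peaks fall in the lower left field.

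Across the 356 IDR peaks found in both replicate lists, the signal values of the replicates had a Spearman rho of 0.13 and a Pearson r of 0.27 on the log2 scale. Peaks are not independent replicates, so no p-value is attached. Every IDR peak was also among the 360 best intervals of the pooled list, so this correlation is over a set chosen on the pooled signal. Over the 9107 pooled intervals found in both replicate lists, a set chosen after seeing the data, rho was 0.26 and r 0.39. Over the union of the 360 best intervals of each replicate rho was 0.016 for the 488 found in both lists, and 93 others were missing from the list of the other replicate. Choosing intervals that are high in either replicate can by itself lower rho, so this value does not measure agreement over all sites.

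IDR peaks lay near the starts of protein-coding genes more often than chance placement. Of 360 summits, 156 were within 500 bp of a protein-coding transcript start (43.3%, 95% Wilson interval 38.3 to 48.5), as at zip-11, tasp-1, kin-14 and prmt-5. Random placement on the same chromosomes gave 22.9% ± 2.20 (SD over 1000 placements; two-sided permutation p = 0.002, the smallest that this number of placements can give). Among 29605 pooled summits outside IDR peaks the share was 26.7% (log2 odds ratio 1.07, Fisher's exact p = 1.85e-11). With the starts of all annotated genes the count was 249 summits (69.2%), against 33.5% ± 2.41 by chance and 37.4% of the other pooled summits. Of the 156 summits, 108 lay upstream of the nearest protein-coding start and 48 at or downstream of it, with a median distance of 190 bp.

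**Figure D2:**
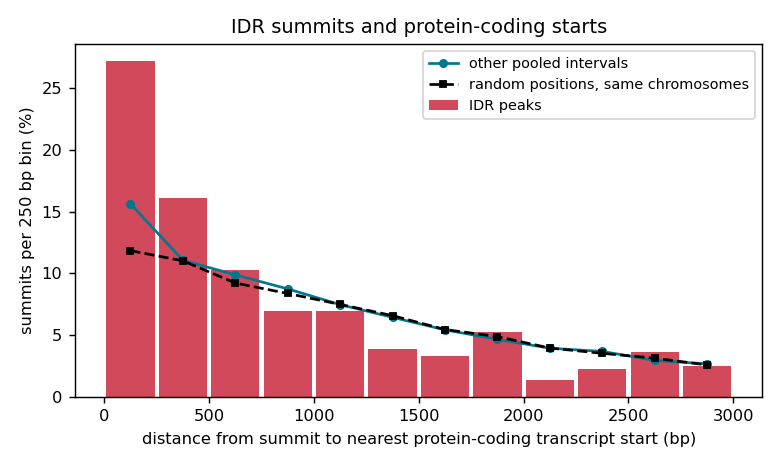
Share of summits in bins of 250 bp by distance to the nearest protein-coding transcript start (horizontal, bp; vertical, percent of summits). Bars show the 360 IDR peaks, circles the 29605 other pooled intervals and squares random positions on the same chromosomes; in the nearest bin the shares were 27.2%, 15.6% and 11.8%.

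Genes of small nucleolar, transfer and small nuclear RNAs were over-represented among target genes, meaning genes with an IDR summit within 500 bp of a start. The background was all genes with any pooled summit in that window. Of 214 snoRNA genes, which guide chemical modification of ribosomal and other RNAs, 46 were targets (21.5% against 2.88% of other genes, log2 odds ratio 3.22, adjusted exact p = 4.84e-24). Besides ZK994.7, C51F7.4 and T03F7.8 these included C51F7.3, 70 bp from the same summit as C51F7.4. Of 458 tRNA genes 42 were targets (9.17% against 2.97%, log2 odds ratio 1.73, adjusted exact p = 6.59e-09). With only the 144 peaks among the 360 best of both replicates, 14 were targets (3.06% against 1.28%, log2 odds ratio 1.33). The adjusted exact p was then 0.0320, the largest over all alternatives for tRNA genes. WBGene00014334 and its neighbour WBGene00014333 shared the peak in him-4, WBGene00000308 had a summit at X:13665588 (signal 106) and WBGene00023140 at III:5295044. Of 68 genes annotated as snRNA 13 were targets (19.1% against 3.11%, log2 odds ratio 2.92, adjusted exact p = 1.42e-06). Without replicate 5, that is, with the 360 best intervals of replicate 6 in place of the IDR peaks, 7 were targets (10.3%, log2 odds ratio 2.03, adjusted exact p = 0.0225, range over all alternatives 9.91e-10 to 0.0225). Of the 13 at IDR peaks, 9 were SL2 RNA genes, among them sls-2.4, sls-2.1, sls-2.2 and sls-2.3. A pooled interval lay within 500 bp of 17 of 18 annotated sls-2 genes and of 0 of 12 sls-1 genes, of the SL1 spliced leader, so sls-1 genes could not have been called targets and the spliced leaders cannot be compared here. All p-values for gene lists are from Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 30 lists. Neighbouring genes can share a peak (the 42 tRNA genes lay at 35 peaks), so genes are not fully independent units.

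Ribosomal protein genes were the only list past the adjusted threshold among the 24 lists of protein-coding genes. Of 45 such genes 10 were targets (22.2% against 2.67%, log2 odds ratio 3.43, adjusted exact p = 1.92e-06). The strongest were rpl-3, rpl-20, rpl-15 and rpl-35, the last with a signal of 112 at III:7854672. Of the 10 peaks, 2 also had a tRNA, snoRNA or snRNA start within 500 bp. The summits counted for rpl-20, rps-19 and rps-26 lay nearer to the start of another protein-coding gene. These genes were Y17G9B.5 (176 against 286 bp), hsr-9 (198 against 247 bp) and tmem-107 (11 against 468 bp). With a window of 250 bp the call was lost (3 of 22 genes, log2 odds ratio 2.73, adjusted exact p = 0.0998, range over all alternatives 1.86e-08 to 0.0998), and several of these summits lay more than 250 bp from the start, as at rpl-3, rpl-20 and rpl-15.

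Counted by gene, piRNA genes, which encode germline small RNAs, were under-represented, but counted by summit, a count chosen after seeing the data, they did not pass the threshold. Of 1813 piRNA genes with a pooled summit in the window 10 were targets (0.552% against 3.63%, log2 odds ratio -2.70, adjusted exact p = 6.16e-15), with 21ur-14981 near the ego-1 peak the strongest. Neighbouring piRNA genes share summits, and a piRNA start lay near 7 of 360 IDR summits (1.94%) against 2.84% of the other pooled summits (log2 odds ratio -0.46, adjusted exact p = 0.526). MicroRNA genes did not pass it by gene, with 5 targets of 126 (adjusted exact p = 0.863), led by cel-mir-253, cel-mir-51 and cel-mir-52, but did by summit, with a start near 6 of 360 IDR summits (1.67% against 0.449%, adjusted exact p = 0.00973). Without replicate 5 there were 8 microRNA targets (adjusted exact p = 0.163, range over all alternatives 0.163 to 1). Of 2 rRNA genes 0 were targets (adjusted exact p = 1).

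Several other lists of protein-coding genes had a higher share of targets than other genes but did not pass the adjusted threshold. Core histones had 3 targets of 18 (adjusted exact p = 0.0648), namely his-37, his-41 and his-35, and without replicate 6 they had 1 (adjusted exact p = 0.815, range over all alternatives 0.0648 to 1). The genes his-41 and his-35 share a summit at V:9545750, so the 3 targets lay at 2 peaks. Heat shock and chaperone genes had 4 of 36 (11.1% against 2.76%, adjusted exact p = 0.0688). These were cct-8, a subunit of the cytosolic chaperonin, hsp-90, dnj-20 and hsp-3, an endoplasmic reticulum chaperone. In place of the IDR peaks, the 360 best intervals of replicate 5, that is, without replicate 6, gave 5 targets and an adjusted exact p of 0.0114 for this list, and those of replicate 6 gave 2 and 0.558. A window of 1000 bp gave 0.0492 and all annotated genes as background 0.0105, within a range of 0.0105 to 0.741 over all alternatives. Genes of the hsp-70 family known by sequence names, such as F44E5.4, are not on that list. Chromatin regulators had 5 of 55 (9.09%, adjusted exact p = 0.0688), including set-16, set-21, lin-9 and lin-53, and an adjusted exact p of 0.0232 against all annotated genes (range over all alternatives 0.0232 to 0.585). Without replicate 6 they had 3 targets (0.479). Of the 5, set-21 and lin-54 share their peaks with rpl-7A and rpl-12, which are nearer to the summits (188 against 66 bp and 383 against 10 bp) and are counted among the ribosomal protein targets. Translation factors and tRNA synthetases had 3 of 32 (the factor genes eef-2 and eif-3.C and the synthetase gene ears-2, adjusted exact p = 0.198), germ granule and germline RNA-binding genes 3 of 40 (ego-1, puf-9 and ifet-1, 0.302), and splicing genes 2 of 26 (lsm-8 and lsm-6, 0.379). Each of these last lists had 1 target without replicate 6, and the list of translation factors and synthetases also without replicate 5. The ifet-1 peak is the one counted at the ribosomal protein gene rps-1.

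None of the remaining lists passed the adjusted threshold, and the share of targets among other genes was 2.79% to 2.86% for each. There were 0 among 101 nuclear hormone receptor genes (adjusted exact p = 0.325), 0 of 88 innate immunity effectors (0.387), 0 of 73 collagen and cuticle genes (0.510), 0 of 50 intestinal genes (0.713), 0 of 27 muscle genes, 0 of 24 proteasome genes, 0 of 17 major sperm protein genes and 0 of 12 yolk and eggshell genes (adjusted exact p = 1 for each of the last 4). Chemoreceptor genes had 2 targets of 210 (sri-5 and srh-269, adjusted exact p = 0.330), and all annotated protein-coding genes as background gave an adjusted exact p of 0.00185 for depletion (range over all alternatives 0.00185 to 1). The neuronal list had 1 of 99, egl-30, which entered it through a symbol pattern (0.824). Homeobox and other developmental regulators had 3 of 87 (3.45%, zip-11, atf-7 and elt-3, 0.961), detoxification genes 2 of 61 (3.28%, gst-9 and gst-27, 0.939) and F-box and MATH-BTB genes 2 of 82 (fbxb-72 and fbxb-85, 1). The summit counted for srh-269 lay nearer to the tRNA gene WBGene00014499 (92 against 358 bp). That for gst-27 lay nearer to the snoRNA gene Y53F4B.48 (60 against 357 bp). Mitochondrial ribosome genes had 2 of 36 (5.56%, mrps-35 and mrpl-41, 0.510), respiration genes 1 of 28 (3.57%, cox-5A, 0.824), cell cycle genes 1 of 37 (cdc-48.1, 1) and meiosis genes 1 of 24 (4.17%, lab-2, 0.824). With either replicate left out, these lists had 0 to 3 targets each and none passed the threshold. With so few targets per list, depletion of the smaller lists was not detectable.

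**Figure D3:**
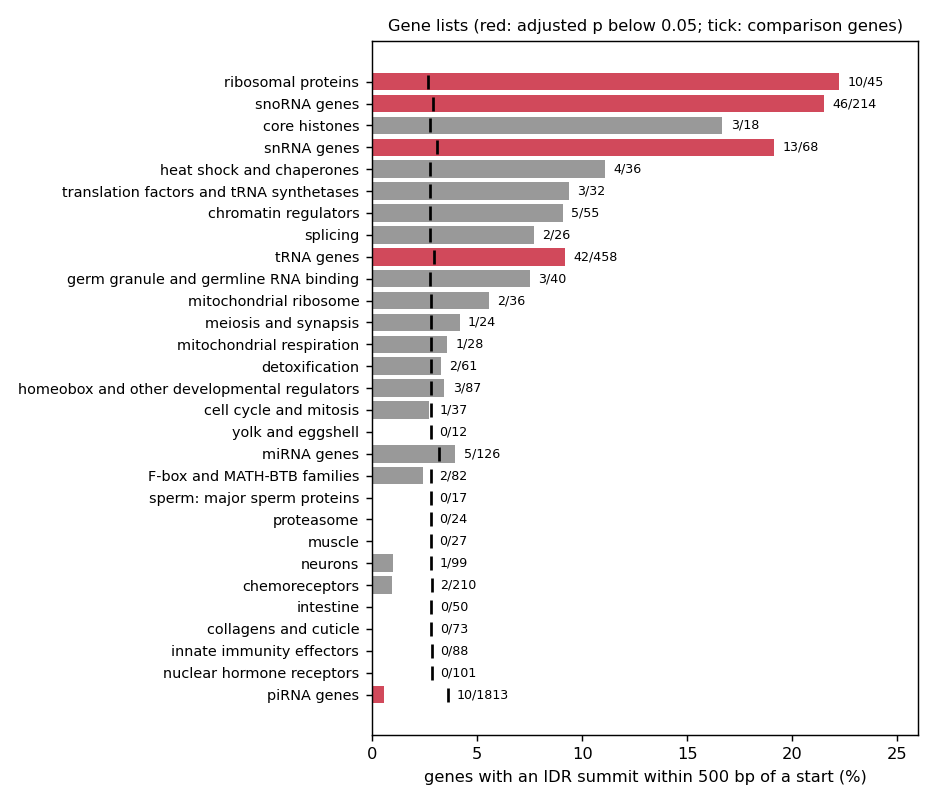
Percent of genes in each list with an IDR summit within 500 bp of a start (bars; horizontal axis, percent), with targets and tested genes beside each bar, for the lists with at least 10 tested genes; the black tick gives the percent for the comparison genes, which were other protein-coding genes for protein-coding lists and all other genes for non-coding classes. Red bars passed the adjusted threshold of 0.05: ribosomal protein, snoRNA, snRNA and tRNA genes lie above their tick and piRNA genes below it.

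No chromosome passed the adjusted threshold against the pooled summits outside IDR peaks (Fisher's exact test with Benjamini-Hochberg adjustment over 6 chromosomes). Chromosome III held 70 peaks (19.4% against 14.8%, log2 odds ratio 0.48, raw p = 0.0170, adjusted exact p = 0.102; without replicate 5 log2 odds ratio 0.025, adjusted exact p = 0.941) and chromosome V 59 (16.4% against 20.6%, -0.40, raw p = 0.0491, adjusted exact p = 0.147; without replicate 6 log2 odds ratio -0.17, adjusted exact p = 0.787). These were the 2 chromosomes with a raw p under 0.05. Chromosome X held 55 peaks (15.3% against 18.6%, adjusted exact p = 0.233), and chromosomes I, II and IV held 60, 56 and 60. With chromosome length as the background, chromosome III passed (exact binomial test, adjusted p = 0.0164, range over all alternatives 0.0164 to 0.941).

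Peak summits were richer in G and C than other pooled summits. Within 100 bp of IDR summits the mean GC content was 43.3% ± 7.48 (SD over 360 peaks), against 40.7% ± 7.14 for the other pooled summits, a difference of 2.64 percentage points (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Flanks 300 bp to either side of the same summits had 35.6%.

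Of 2080 tested 6-mers, both strands collapsed, 185 were more frequent within 50 bp of summits than in the flanks and 97 less frequent at an adjusted p under 0.05 (Fisher's exact test, Benjamini-Hochberg). This test ignored the pairing of each summit with its own flanks. The windows were therefore not independent, and these p-values are approximate. CGAGAG was present at 14.2% of summits and 2.50% of flanks (adjusted exact p = 1.43e-09), GGCCAC at 10.3% and 1.11% (3.84e-09), GCAGAC at 9.72% and 1.25% (5.17e-08) and AGCGCG at 10% and 1.53% (1.50e-07). The overlapping 6-mers ACGCAG and GACGCA were at 10.3% and 10% of summits against 1.81% of flanks for each. A/T runs were depleted, with AAAAAT at 24.2% of summits and 52.2% of flanks and AAAAAA at 19.4% and 40.1%. The flanks were lower in GC than the summits, and against other pooled summits 121 6-mers were enriched and 31 depleted. Leaving out replicate 6 gave 107 enriched and 61 depleted 6-mers. No single 6-mer was present at more than 14.2% of summits among the enriched ones shown.

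**Figure D4:**
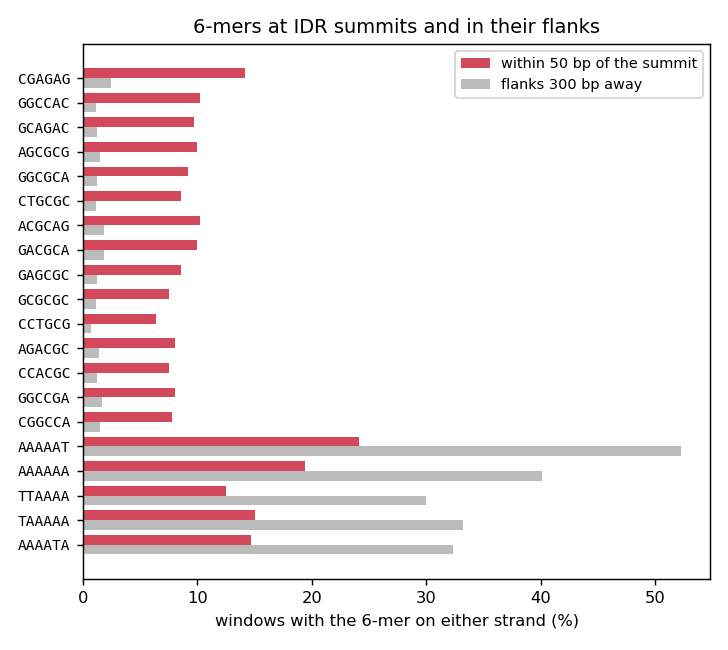
Percent of windows holding each 6-mer on either strand (horizontal axis), for the 15 most enriched and the 5 most depleted 6-mers by p-value. Red bars are the 360 windows within 50 bp of IDR summits and grey bars the 720 flank windows 300 bp away; enriched 6-mers reach 14.2% and depleted A/T-rich 6-mers run from 12.5% to 24.2% at summits.

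At the tagged gene itself, F57C9.4 (WBGene00019011, I:4830135-4835622, plus strand), 1 IDR peak lay within 1000 bp. Its summit at I:4829243 was 892 bp upstream of the gene, in a coding exon of the neighbouring gene htp-3, whose product is a meiotic chromosome axis protein. It ranked 350 of 30000 in the pooled list, near the end of the 360 IDR peaks, with a signal of 67.3. Its rank was 310 in replicate 5 and 2761 in replicate 6, and it was not among the stronger 180 peaks. The region held 24 pooled intervals within 20 kb of the gene, against a median of 13 for protein-coding genes (percentile 96.5). unc-119 (WBGene00006843, III:10902641-10908935), the gene mutated in the strain, had no IDR peak within 1000 bp. Its best pooled interval ranked 7181, and 10 pooled intervals lay within 20 kb (percentile 26). Extra transgene copies can raise reads over the tagged gene, so this peak is not evidence of binding by itself.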

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

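Alternatives that used peaks in both replicates' best intervals, peaks without small RNA starts, all pooled intervals, or summits away from tRNA starts were chosen after seeing the data. Of the main results, 35 alternatives left the value on its side of the threshold or within its spread and 25 moved it; of single chromosomes and gene lists, 238 were the same, 8 passed the threshold only under the alternative, 1 (ribosomal proteins at 250 bp) no longer passed and 30 changed sign without being past the threshold under either setting. These log2 odds ratios were, for the stronger 180 peaks, -0.039 for chromosome II, 0.45 for proteasome, -0.13 for mitochondrial ribosome, 0.94 for major sperm protein, 0.28 for muscle and -0.89 for detoxification genes. With replicate 6 or 5 left out, the ranges were -0.020 to 0.38 for chromosome II, 0.078 to 1.84 for major sperm protein, -0.49 to 1.07 for muscle, -2.45 to 0.52 for neuronal, -1.46 to 0.25 for intestinal, -1.66 to 0.64 for detoxification and -0.56 to -0.48 for F-box genes. At 250 bp they were 0.31 for proteasome, -0.45 for germline RNA-binding, 0.53 for major sperm protein and 0.040 for muscle genes, and at 1000 bp 0.53 for major sperm protein, -0.17 for detoxification and -0.24 for F-box genes. All annotated genes as background gave 0.65 for proteasome, 0.27 for muscle and -0.77 for F-box genes, and peaks among the best of both replicates gave 0.76 for proteasome, 1.25 for major sperm protein, 0.59 for muscle and -0.57 for detoxification genes. Chromosome IV had -0.070 against chromosome length. For a list with 0 targets the sign comes from the 0.5 added to each cell. The share of IDR peaks found in replicate 5 was 86.7% among its 720 best intervals, 99.7% in its whole list and 92.8% for the stronger 180 peaks; for replicate 6 these were 73.1%, 99.2% and 80.0%, and 53.9% with summits within 100 bp. The deeper lists raise the share by construction. Replicate rho was 0.016 over the union of best intervals, a choice that can by itself lower it. It was 0.26 over the 9107 of 30000 pooled intervals found in both replicate lists. The number of chromosomes past the threshold, 0 as reported, was 1 with chromosome length as background and 2 without tRNA summits. All annotated genes as background gave 8 called gene lists in place of 5. Enriched 6-mers numbered 76 for the stronger 180 peaks, 107 to 128 with a replicate left out, 57 within 25 bp, 121 against pooled summits, 51 for peaks among the best of both replicates and 97 without small RNA starts; depleted ones numbered 38, 61 to 69, 41, 31, 26 and 40. Fewer peaks tested account for part of the lower counts by construction; otherwise the cause was not tested. The stronger 180 peaks held 0 at F57C9.4 in place of 1. No paired analysis was possible because there is 1 group. Read depth is unknown, so what it limits was not tested.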

Other observations

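The tests of ribosomal protein genes and of chromosome X below were chosen only after the results had been seen, as were the positions of summits in annotated features and the classes of nearby starts. By annotated feature, 159 of 360 summits were intergenic (44.2% against 25.7% of 2000 sampled background summits) and 62 in non-coding exons (17.2% against 3.85%), with Fisher's adjusted exact p of 9.07e-12 and 2.88e-17. In coding exons there were 49 (13.6% against 37.7%) and in introns 60 (16.7% against 28.6%), with 3.03e-20 and 1.71e-06. The 5′ untranslated regions, as at zip-11 and kin-14, held 15 (4.17% against 1.45%, Fisher's adjusted exact p = 0.00244). The 3′ untranslated regions, as at zig-11, also held 15 (4.17% against 2.75%, 0.174). A tRNA, snoRNA or snRNA start lay within 500 bp of 91 summits (25.3% against 2.35% of the background, log2 odds ratio 3.81, adjusted exact p = 1.82e-61), with a median distance of 47 bp. A start of another annotated non-coding RNA gene lay within 500 bp of 80 summits (22.2% against 8.45%, log2 odds ratio 1.64, adjusted exact p = 5.56e-15), as at rpr-1, and the classes can overlap. Of the 91, 64 had no protein-coding start in that window, as at ZK994.7 in pxn-1, while 129 of the 360 had a protein-coding start and no small RNA start, and 111 had no annotated start of any kind. The median signal was 84.3 for peaks near a small RNA start and 80.3 for the others.

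Peaks near tRNA starts lay mostly on chromosome X, where 276 of the 612 annotated tRNA genes are. Of 35 such peaks 23 were on X (65.7%), against 41.9% of 427 background summits near tRNA starts, a difference that was not tested. With tRNA summits left out of peaks and background, X held 32 peaks (9.85% against 18.2%, log2 odds ratio -1.01) and chromosome III 67 (20.6% against 14.9%, log2 odds ratio 0.58). The positions of the tRNA peaks were known before these summits were left out, so the lower share on X follows in part from the subtraction and is given as a description. No biological explanation for it was tested.

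tRNA, snoRNA and snRNA genes as targets could reflect neighbouring protein-coding starts or base composition. Among the 440 such genes more than 1000 bp from a protein-coding start 54 were targets (12.3% against 2.55%, log2 odds ratio 2.43, 95% interval 1.99 to 2.87, Fisher's exact p = 7.87e-20), which argues against shared starts as the whole cause. With summits matched in 10 GC bins the Mantel-Haenszel odds ratio was 13.5 (95% interval 10.4 to 17.3), close to 14.0 without matching, which argues against GC content. Open is a signal at heavily transcribed genes in general, of the tagged protein or of any precipitated chromatin: ribosomal protein genes had a log2 odds ratio of 3.43, but this value was known before the test was chosen and transcript levels were not analysed here. Other tagged proteins and untagged worms were not analysed here, so binding by F57C9.4 and such a general signal cannot be told apart.

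The signal around F57C9.4 may come from extra copies of the region in the integrated transgene. The number of pooled intervals within 20 kb of F57C9.4 was at percentile 96.5 of protein-coding genes (94.5 in replicate 5 and 97.6 in replicate 6). The rule set in advance for that explanation required both F57C9.4 and unc-119 above percentile 99. The rule against it required F57C9.4 at or below 95. In the pooled list neither was met, so transgene copies and binding cannot be told apart. Replicate 5 alone lay below 95, while replicate 6 lay above it. unc-119, at percentile 26, showed no such rise. Whether the transgene holds the worm's own unc-119 sequence is not stated in the labels.

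IDR summits lay in the middle 50% of the autosomes in 177 of 305 cases (58.0% against 51.2% of background summits, log2 odds ratio 0.40, Fisher's exact p = 0.0182), while target genes lay there in 99 of 174 (56.9% against 54.6%, log2 odds ratio 0.13, 95% interval -0.31 to 0.57, p = 0.589). The interval includes 0.40, so a difference of that size between target and other genes was not excluded, and gene density remained open. The count of 174 is close to that of protein-coding targets on all chromosomes (188) and far below that of all classes (409). The summits were not limited to protein-coding starts, so the summit and gene ratios need not cover the same sites.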
